A study of Homo sapiens with 6 samples.

How the data were processed

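Messenger RNA abundance was measured by RNA sequencing in MCF-7, an estrogen receptor-positive human breast cancer cell line grown in DMEM with fetal bovine serum. There were 6 libraries, 3 from cells carrying a control shRNA and 3 from cells carrying an shRNA against YEATS4. Total RNA was extracted with TRIzol and made into standard Illumina libraries, per the labels' protocols. The deposited table holds whole-number read counts per Ensembl gene, not normalized, for all 6 libraries. The submitters' processing notes name HISAT2, DESeq2 and the genome build hg19, with no version or role. The read counter, the gene annotation, the strand setting and any filter are not given in the sources used here. Because the strand setting is not given, reads of a gene and of an overlapping antisense gene cannot be told apart. The handling of reads that match several genes is not given either, so counts of near-identical genes, such as ribosomal protein genes with processed pseudogenes, histone genes and keratin 6 genes, are uncertain. Columns were assigned to libraries by name. The control columns carry the abbreviation and number of the control titles, and the others, marked sh and a number, were read as the YEATS4 shRNA libraries of that number.

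Library totals ran from 11678866 to 13989644 counts, and 3 counts in a library, taken as the limit that a count of 0 allows, corresponded to 0.214 to 0.257 counts per 1000000 (CPM). Such limits cover counting error only. The table listed 57820 genes, of which 31586 had at least 1 count. Gene symbols came from a table of gene names for 51996 identifiers and from GENCODE 29 for 342. The other 5482 had no symbol and held 0.709% of all counts. Identifiers that shared a symbol with a more abundant one, 896 in all, kept their identifier as name. The gene annotation at hand is for GRCh38, not for hg19, so it was used for names, gene types, chromosome names, transcript length and GC content, and no coordinates are given. All 2636 genes that it places on chromosomes X and Y and on the mitochondrial genome had 0 counts in every library, whereas 16113 of 18423 protein-coding genes elsewhere (87.5%) had counts. X-linked, Y-linked and mitochondrial transcripts were therefore not analysed here.

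Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default minimum count of 10, library sizes were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood model with robust spread estimates was fitted to the group alone, with 3 libraries in each group. The quasi-likelihood F test was adjusted by the Benjamini-Hochberg method over the 15164 genes kept, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were taken from the fold change and its F statistic. CPM values use the TMM-scaled library sizes, and CPM is given as mean ± SD over the 3 libraries of a group. Fold changes are knockdown over control throughout.

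Before the data were examined, 24 gene lists with 713 entries, the comparison, the tests, the alternative settings and the rule for naming genes were fixed. The table held 699 of the entries; ACACA and UHRF1 were among those not analysed here. Each list with at least 5 tested genes was compared with all other genes by camera in limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 and a 2-sided test adjusted over 22 lists. Camera was repeated with the correlation estimated for each list, which also leaves the test fewer degrees of freedom. The directional test fry was run, which asks whether a list moves on balance one way without comparing it with other genes. The members of each list were counted as higher, lower or not called over all genes tested and, separately, adjusted over the list alone. The text names YEATS4 and the 12 largest rises and 12 largest falls among called genes with a mean CPM of at least 5 and no overlap between the groups. It also names up to 4 members of each list with the smallest adjusted p, or up to 8 for the fatty acid and stemness lists. Other genes are said to be chosen after their values were seen.

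The tests were checked on counts simulated from the means, spread and library sizes of these libraries, with 50 genes changed at each fold size. Over 14971 simulated genes, edgeR recovered 64% of genes changed 1.2-fold, 80% of those changed 1.5-fold, 90% of those changed 2-fold and 96% of those changed 3-fold, and 7.3% of its 191 calls were false. A far smaller share of genes changed in the simulation than the 27.3% called in the real libraries, so its adjusted threshold was stricter. These recoveries therefore do not carry over directly to the real comparison. A simulated list of 30 genes raised 1.2-fold was called by camera, and an unchanged list of 30 genes was not. Simulated genes were drawn independently of one another, whereas the estimated correlation in the real ribosomal protein list was 0.189. This check therefore does not show how often camera calls unchanged lists of correlated genes. Every pair of libraries within a group differed by more than sampling noise, with a chi-square of 1.45 to 2.81 per gene, so none was treated as a repeat deposit of another, although this does not show that they were independent samples. The labels do not say whether the 3 libraries of a group came from separate cultures. The alternatives were DESeq2 size factors, upper-quartile factors (not run for the gene lists) and library size alone in place of TMM, no low-count filter and a stricter one, DESeq2 1.42.0 and limma-voom in place of edgeR, a fit without robust spread estimates, a test against a 1.2-fold change, the replicate number as a block, and leaving out each library in turn. The DESeq2 run started from all 31586 genes with a count and used its own size factors and filter. It gave 14439 of them an adjusted p. After the data were seen, a correction of each library for GC content and transcript length and a scaling without the ribosomal protein, mitosis and interferon genes were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.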

Results

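RNA sequencing libraries of MCF-7 breast cancer cells carrying a control shRNA (3 libraries) or an shRNA against YEATS4 (3 libraries) were compared. YEATS4, also called GAS41, is a chromatin protein with a YEATS domain, which binds acylated histone tails, and a subunit of the SRCAP and TIP60 chromatin complexes. The series asks which transcripts depend on YEATS4, with fatty acid metabolism and stemness named in its title. Total counts were 11678866, 13203786 and 13313714 in the control libraries and 12153839, 11874260 and 13989644 in the knockdown libraries. Between 23829 and 24612 genes were detected per library. After the low-count filter, 15164 genes were tested.

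The targeted gene was measured first. YEATS4 (ENSG00000127337.2) had 283, 302 and 359 counts in the control libraries and 84, 71 and 96 in the knockdown libraries. Its level was 24.3 ± 2.07 CPM in control and 6.71 ± 0.526 CPM in knockdown cells (SD, n = 3 each). This was a change of -72.3% (log2 fold change -1.85, SE 0.11, edgeR quasi-likelihood adjusted p = 1.13e-25).

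In YEATS4 knockdown cells, interferon-response genes were lower as a group. Genes of mitosis, DNA replication, ribosomal proteins, cholesterol synthesis and the estrogen response were higher. The lists differed from other genes at camera adjusted p of 3.84e-23 to 8.35e-05, but for ribosomal proteins, cholesterol synthesis and the estrogen response the call was lost at adjusted p = 0.205, 0.143 and 0.147 with an estimated correlation. Most shifts were small. Over the genome, 4137 of the 15164 genes (27.3%) changed by the edgeR quasi-likelihood test, 2148 upward and 1989 downward, and their median change in either direction was 1.21-fold. Of these, 709 changed at least 1.5-fold (242 up, 467 down) and 226 at least 2-fold (89 up, 137 down). The control and knockdown libraries did not overlap in 3881 of the called genes, and in 38.7% of all tested genes against 10% by chance. Scaling by library size alone gave 4287 calls, of which 32.6% were higher, against 51.9% with TMM. The DESeq2 Wald test, run with its own filter and size factors, called 2508 genes, and an edgeR test against a 1.2-fold change called 729.

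The largest rise among abundant enough genes was that of CMAHP, the transcribed human pseudogene of a sialic acid hydroxylase, from 2.32 ± 0.0338 to 10.8 ± 1.13 CPM (log2 fold change 2.20, SE 0.17, edgeR adjusted p = 6.91e-20). MUC5AC, a gel-forming mucin, rose 4.52-fold (log2 fold change 2.18, SE 0.14, edgeR adjusted p = 3.59e-23), and KRT6A, an epithelial keratin with near-identical relatives, rose 3.44-fold. The other 9 rises included the non-coding RNAs LINC01522 (2.91-fold), LINC00052 (2.43-fold) and an unnamed processed transcript, ENSG00000253154 (3.05-fold). PRODH, which starts proline breakdown, rose 2.50-fold, the secreted protease ADAMTS9 2.48-fold, the heparan sulfate sulfotransferase HS3ST3A1 2.44-fold, the poly(A) polymerase TENT5C 2.39-fold and the carbonic anhydrase-related CA8 2.37-fold. TFF1, a secreted trefoil peptide and a classical estrogen receptor target, rose from 431 ± 7.21 to 1016 ± 29.3 CPM, and its edgeR adjusted p of 1.23e-54 was the smallest of the genes named here.

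Several of the largest falls were of members of the interferon-response list. IFI44L dropped from 43.2 ± 4.54 to 12.7 ± 1.62 CPM (log2 fold change -1.76, SE 0.09, edgeR adjusted p = 1.55e-28), and IFIT3, an antiviral RNA-binding protein gene, had a log2 fold change of -1.72. IFI44, BST2 and XAF1 of the same list, and CMPK2, PARP10 and DDX60L, which interferon also induces, had log2 fold changes between -1.56 and -1.29. The other falls were SEMA3D, a secreted guidance factor (log2 fold change -1.56, SE 0.09), DNM3, a dynamin (-1.35, SE 0.17), and PMP22, a membrane protein of myelin (-1.32, SE 0.16). CMPK2 and XAF1 rested on few reads, with 30 to 35 and 29 to 43 counts in the knockdown libraries. None of these 24 genes lost its call in any alternative fit that tested against no change.

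**Figure D1:**
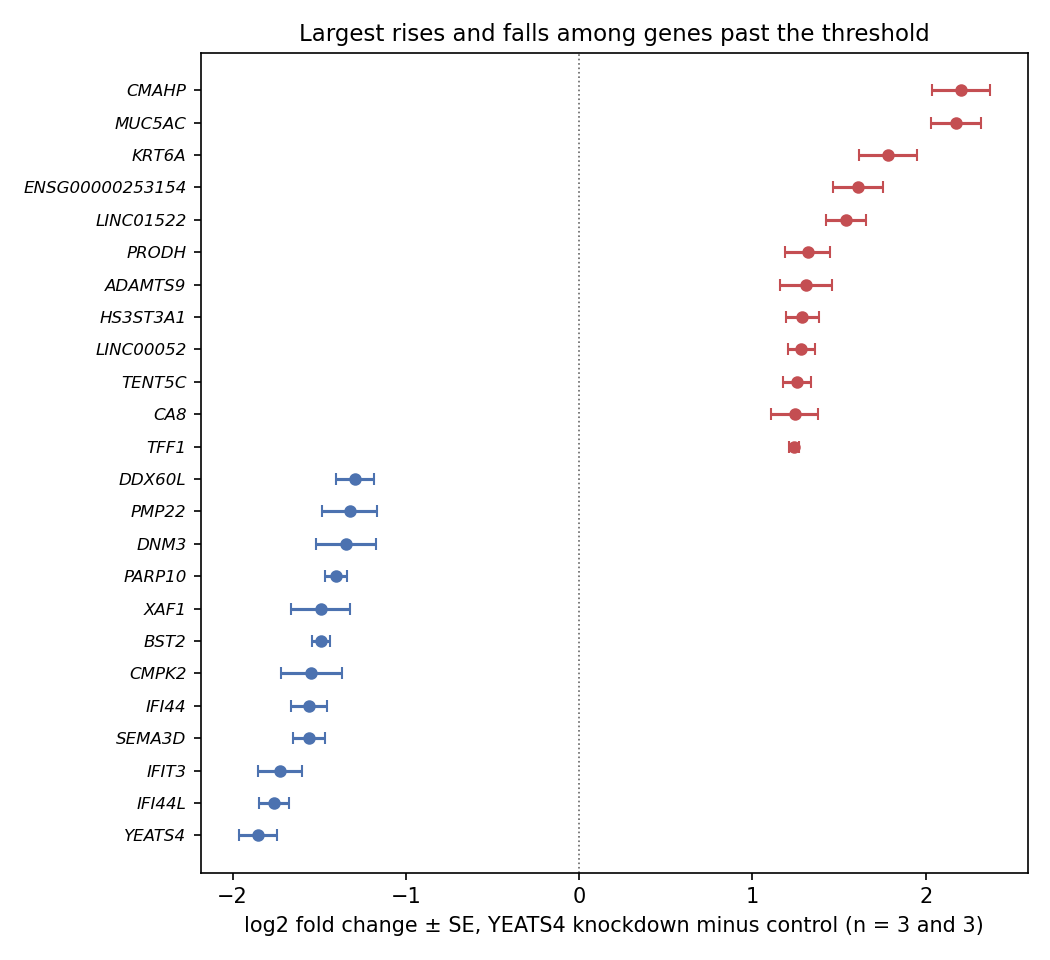
The 12 largest rises (red) and 12 largest falls (blue) among called genes that met the naming rule. That rule asks for a mean CPM of at least 5 and no overlap between the groups. The horizontal axis gives the log2 fold change of YEATS4 knockdown over control with SE, from 3 libraries in each group. The rises run from 1.24 (TFF1) to 2.20 (CMAHP) and the falls from -1.29 (DDX60L) to -1.85 (YEATS4).

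Interferon-response genes were lower in the knockdown with little exception. Of 36 tested members, 35 fell and 1 rose (35 and 1 adjusted over the list alone), with a median log2 fold change of -0.66. BST2, which tethers budding virus particles, dropped from 118 ± 5.62 to 42.2 ± 2.70 CPM (edgeR adjusted p = 7.13e-41). ISG15, a ubiquitin-like modifier, dropped from 334 ± 3.69 to 199 ± 10.9 CPM, IFIT1 had a log2 fold change of -0.90 and OAS3, which makes the activator of RNase L, had one of -0.66. The single rise was ISG20, an exonuclease gene chosen after its values were seen (log2 fold change 0.46, SE 0.08, edgeR adjusted p = 1.03e-06). Camera gave the list an adjusted p of 3.84e-23, and an adjusted p = 0.0413 with an estimated correlation. Of the 22 lists tested, this list, the mitosis list and the DNA replication list held their calls with an estimated correlation, and no other of the 22 did.

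**Figure D2:**
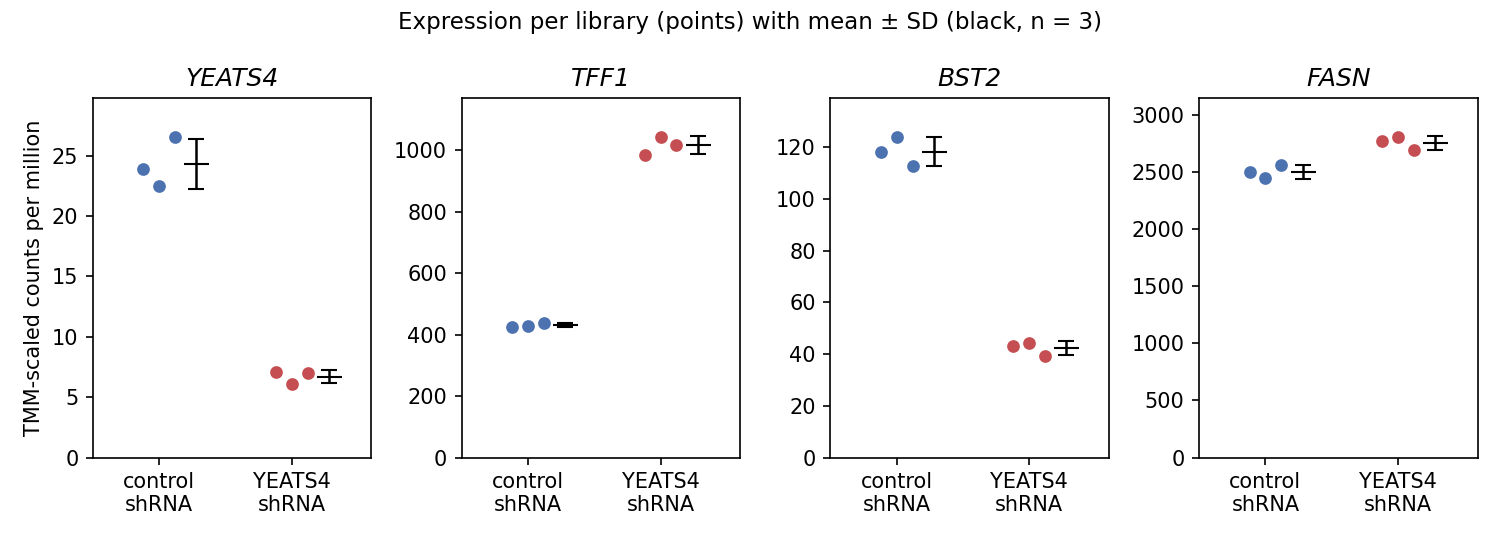
TMM-scaled CPM (vertical axes, from 0) of YEATS4, TFF1, BST2 and FASN in each control (blue) and YEATS4 knockdown (red) library, with mean ± SD in black (n = 3). In knockdown libraries TFF1 lay between 985 and 1044 CPM against 424 to 438 in control libraries, and BST2 between 39.1 and 44.2 CPM against 113 to 124.

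Genes of mitosis were higher almost throughout. All 40 members were tested, 38 rose and 0 fell (39 and 0 adjusted over the list alone), and the median log2 fold change was 0.28 (camera adjusted p = 2.09e-18, and adjusted p = 0.0413 with an estimated correlation). The mitotic kinase PLK1 rose from 204 ± 1.41 to 286 ± 6.70 CPM, the topoisomerase TOP2A 1.30-fold, the cytokinesis scaffold ANLN 1.42-fold and the checkpoint protein BUB3 1.29-fold. DNA replication genes moved less, with 17 of 40 higher and 1 lower (20 and 1 adjusted over the list alone) and a median of 0.13 (camera adjusted p = 6.94e-06, and adjusted p = 0.0413 with an estimated correlation). The replicative helicase subunits MCM6 and MCM7 rose 1.37-fold and 1.15-fold, the nucleotide reductase RRM2 by 19.8% and the sliding clamp PCNA 1.18-fold. Of 10 replication-dependent histone genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone), among them H2AC6 (log2 fold change 0.26, SE 0.06) and H1-2 (0.28, SE 0.07), with camera adjusted p = 0.0381 and adjusted p = 0.248 with an estimated correlation. The third, H4C8, had an edgeR adjusted p of 0.0183 and lost its call under DESeq2 (adjusted p = 0.104), with library-size scaling (edgeR adjusted p = 0.0751), with the GC and length correction (0.0643) and without control replicate 1 (0.0917), knockdown replicate 1 (0.0733) or knockdown replicate 2 (0.0505). The histone list lost its call without control replicate 1 (camera adjusted p = 0.109), control replicate 2 (0.0589) or knockdown replicate 1 (0.122), and with the GC and length correction (0.234).

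Ribosomal protein genes rose together by small amounts. Of 45 tested, 35 rose and 0 fell (37 and 0 adjusted over the list alone), with a median log2 fold change of 0.14 (camera adjusted p = 8.68e-11, but adjusted p = 0.205 with an estimated correlation). RPS2, RPL8, RPL15 and RPL35 rose between 1.16-fold and 1.17-fold. Ribosomal protein genes took 4.26 ± 0.031% of counts in control libraries and 4.59 ± 0.051% in knockdown libraries (SD, n = 3 each). Across the 15164 tested genes, which are not independent replicates, the log2 fold change was higher for more abundant genes (Spearman's rho 0.169 with mean log2 CPM). The 10 genes with the most counts took 4.12 ± 0.031% of counts in control and 4.59 ± 0.032% in knockdown libraries (SD, n = 3 each). Genes of ribosome assembly and other MYC targets had 12 of 28 members higher and 1 lower (12 and 2 adjusted over the list alone), with a median of 0.09 (camera adjusted p = 0.0264, but adjusted p = 0.248 with an estimated correlation). The nucleolar proteins NPM1, NCL and NOP56 rose 1.15-fold, 1.11-fold and 1.15-fold, and the nucleolar GTPase GNL3 1.19-fold. This list lost its call without control replicate 2 (camera adjusted p = 0.0615) and under scaling by library size alone (camera adjusted p = 0.0771).

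Genes of fatty acid synthesis moved in both directions. Of 26 tested, 9 rose and 5 fell (10 and 5 adjusted over the list alone), and camera did not call the list (median log2 fold change 0.020, camera adjusted p = 0.409). Fry, which asks only whether the members moved on balance one way, called it upward (adjusted p = 0.00249). ACACB, the acetyl-CoA carboxylase of the mitochondrial surface, rose from 10.8 ± 1.67 to 22.5 ± 0.855 CPM (log2 fold change 1.05, SE 0.10, edgeR adjusted p = 2.59e-14). The abundant synthesis genes FASN, SCD and ACLY rose 1.10-fold, 1.13-fold and 1.10-fold, and the elongase ELOVL5 1.31-fold. Across all tested genes fold changes were higher at higher levels (Spearman's rho 0.169). FASN, SCD and ACLY were not compared with genes of like level. MLXIPL, a carbohydrate-sensing transcription factor, had a log2 fold change of -0.57 (SE 0.09), the phosphatidate phosphatase LPIN1 of -0.39 (SE 0.06) and the desaturase SCD5 of -0.34 (SE 0.07), each past the edgeR threshold. The median was negative under scaling by library size alone (-0.031), which lowered the median of all tested genes from -0.0034 to -0.054, and with the GC and length correction (-0.0086), which lowered that median to -0.018.

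Most genes of fatty acid uptake and oxidation did not pass the test, as was so of all tested genes, of which 27.3% were called. Of 39 tested, 4 rose and 7 fell (4 and 7 adjusted over the list alone), and the list was not called (camera adjusted p = 0.759). Its median log2 fold change was 0.0059, while its mean was -0.06 and camera pointed downward. CRAT, carnitine acetyltransferase, rose 1.97-fold (log2 fold change 0.98, SE 0.14, edgeR adjusted p = 8.81e-09). Falls were seen for the peroxisomal oxidase ACOX1 (log2 fold change -0.36, SE 0.06), the dehydrogenase ACADL (-1.14, SE 0.24), the fatty acid receptor CD36 (-0.64, SE 0.14), CPT1C (-0.83, SE 0.18) and the thiolase ACAA2 (-0.42, SE 0.11), all at an edgeR adjusted p of at most 0.00125. ACADL, CD36 and CPT1C were low, at 3.81, 10.2 and 6.17 CPM in control cells. EHHADH (edgeR adjusted p = 0.0108) and ACSL1 (0.0162) were called less firmly, and DESeq2 called neither (adjusted p = 0.0912 and 0.116). The EHHADH call was also lost without control replicate 3 (edgeR adjusted p = 0.0877) or knockdown replicate 3 (0.0535), and the ACSL1 call without control replicate 1 (0.0942) or knockdown replicate 2 (0.086). CPT1A, the main entry enzyme of mitochondrial oxidation and chosen after its values were seen, had 138 CPM in control and 136 CPM in knockdown cells. The list's median lay between -0.037 and 0.017 when single libraries were left out, below 0 without control replicate 2 (-0.0036), control replicate 3 (-0.024) or knockdown replicate 2 (-0.037).

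Stemness genes also moved in both directions. Of 28 tested, 6 rose and 9 fell (8 and 11 adjusted over the list alone), with a median log2 fold change of -0.13 (camera adjusted p = 0.409); camera pointed downward and fry upward. CD44, a hyaluronan receptor, rose from 81.4 ± 2.25 to 127 ± 2.76 CPM (log2 fold change 0.64, SE 0.04, edgeR adjusted p = 6.21e-22). The chemokine receptor CXCR4 rose 1.86-fold, the Notch ligand JAG1 1.79-fold, the drug efflux pump ABCG2 2.05-fold and the transcription factor KLF4 1.34-fold. The transcription factors MYC, SALL4 and SOX2 were lower, with log2 fold changes of -0.45 (SE 0.04), -0.68 (SE 0.08) and -0.32 (SE 0.05) and edgeR adjusted p of at most 2.20e-08. None of these 8 genes lost its call in any alternative fit that tested against no change.

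Cholesterol synthesis genes were higher. Of 23 tested, 16 rose and 1 fell (18 and 1 adjusted over the list alone), with a median log2 fold change of 0.22 (camera adjusted p = 2.50e-07, but adjusted p = 0.143 with an estimated correlation). The LDL receptor gene LDLR rose from 165 ± 4.20 to 262 ± 4.64 CPM, the rate-limiting reductase HMGCR 1.47-fold, the sterol-regulated anchor protein INSIG1 1.36-fold and the squalene epoxidase SQLE 1.34-fold. Glycolysis and hypoxia genes had 11 of 26 members higher and 3 lower (12 and 3 adjusted over the list alone) and a median of 0.14 (camera adjusted p = 0.00276, but adjusted p = 0.248 with an estimated correlation). ALDOA, ENO1, LDHA and GAPDH, enzymes of glycolysis, rose 1.26-fold, 1.19-fold, 1.21-fold and 1.15-fold; these are abundant genes, and fold changes were higher at higher levels across all genes (Spearman's rho 0.169). Nuclear genes of oxidative phosphorylation had 10 of 33 members higher and 1 lower (11 and 1 adjusted over the list alone) and a median of 0.07 (camera adjusted p = 0.0264, but adjusted p = 0.248 with an estimated correlation). COX6C rose 1.22-fold, ATP5MC3 by 20.4% and ATP5F1B 1.14-fold, while the complex I subunit NDUFV1 was the single fall (log2 fold change -0.20, SE 0.04). That list lost its call without control replicate 2 (camera adjusted p = 0.0562), control replicate 3 (0.0559) or knockdown replicate 2 (0.0783), with library-size scaling (0.105) and with the GC and length correction (0.215).

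Estrogen-response genes were higher on balance. Of 35 tested, 22 rose and 6 fell (22 and 6 adjusted over the list alone), with a median log2 fold change of 0.17 (camera adjusted p = 8.35e-05, but adjusted p = 0.147 with an estimated correlation). Besides TFF1, the receptor kinase RET rose from 119 ± 0.707 to 191 ± 7.08 CPM, the secreted glycoprotein STC2 1.48-fold and the transcription factor XBP1 1.35-fold. Luminal epithelial genes had 12 of 24 members higher and 7 lower (14 and 7 adjusted over the list alone) and a median of 0.13 (camera adjusted p = 0.0264, but adjusted p = 0.342 with an estimated correlation). The adhesion protein CDH1 rose 1.30-fold, the transcription factor SPDEF 1.58-fold and the keratin KRT8 by 19.9%. KRT8 had the most counts of the genes with counts, which include no X-linked or mitochondrial gene, with 0.923 ± 0.0042% of counts in control and 1.07 ± 0.011% in knockdown libraries (SD, n = 3 each). The luminal list lost its call without knockdown replicate 2 (camera adjusted p = 0.0539).

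Many basal and mesenchymal genes were too low to test. Of 14 tested, 3 rose and 2 fell (3 and 2 adjusted over the list alone) and the list was not called (camera adjusted p = 0.744). Its median log2 fold change was -0.06 but its mean was 0.10 and camera pointed upward; the median lay between -0.015 and 0.15 when single libraries were left out, above 0 without control replicate 2 (0.035), knockdown replicate 2 (0.15) or knockdown replicate 3 (0.15). Besides KRT6A, the matrix protein TGFBI rose 1.69-fold and the integrin ITGA5 1.35-fold, whereas the actin-binding TAGLN was lower (log2 fold change -0.84, SE 0.21), as was the matrix protein FN1, chosen after its values were seen (-0.18, SE 0.05). Among fibroblast and stromal markers 6 were tested, 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.736, pointing downward; fry adjusted p = 0.0127, pointing upward). COL3A1, a fibrillar collagen chain, rose from 186 ± 5.63 to 419 ± 11.7 CPM (log2 fold change 1.17, SE 0.03, edgeR adjusted p = 1.89e-47), and COL5A1 had a log2 fold change of -0.53 (SE 0.05). COL1A1, which was not called, was at 46.8 ± 4.89 CPM in control and 43.2 ± 2.84 CPM in knockdown cells, and passed the threshold downward without control replicate 3 (edgeR adjusted p = 0.0224) and with library-size scaling (0.0452). Of the blood and immune markers 1 gene, ITGAM, was abundant enough to test and was not called (5.67 ± 0.764 and 7.29 ± 0.298 CPM), although it was called without control replicate 2 (edgeR adjusted p = 0.0307) and when adjusted over the list alone. No mitochondrially encoded transcript of the 15 listed had counts.

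Of the p53, unfolded protein, NF-kB and immediate early lists, camera called none. Targets of p53 had 7 of 29 members higher and 2 lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.89), with a negative median of -0.047 although camera pointed upward. The p53 antagonist MDM2 rose 1.16-fold, PLK2 and PPM1D rose 1.22-fold and 1.14-fold, and ZMAT3, an RNA-binding protein gene, was lower (log2 fold change -0.29, SE 0.06, edgeR adjusted p = 1.52e-04). In the unfolded protein and integrated stress response list, 12 of 31 rose and 4 fell (12 and 4 adjusted over the list alone; median 0.05, camera adjusted p = 0.101), and fry, which does not compare the list with other genes, called it upward (adjusted p = 0.00189). The pseudokinase TRIB3 rose 1.47-fold, and the serine synthesis enzyme PHGDH was lower (log2 fold change -0.56, SE 0.05, edgeR adjusted p = 3.06e-17). NF-kB targets had 0 of 16 higher and 4 lower (0 and 4 adjusted over the list alone; median -0.07, camera adjusted p = 0.162). TNFAIP2 was among the 4 (log2 fold change -0.21, SE 0.05), and TNFAIP3, IRF1 and CXCL10 were not called by DESeq2 (adjusted p = 0.0718, 0.123 and 0.227), and CXCL10 also lost its edgeR call with no low-count filter (adjusted p = 0.0935). Without single libraries their edgeR adjusted p reached 0.101 for TNFAIP3 (without control replicate 1; also lost without knockdown replicate 1), 0.134 for IRF1 (knockdown replicate 1; also control replicate 3 and knockdown replicate 3) and 0.181 for CXCL10 (knockdown replicate 3; kept only without control replicate 2). Immediate early genes had 10 of 24 higher and 5 lower (11 and 5 adjusted over the list alone; median 0.17, camera adjusted p = 0.081). The growth-factor-induced EGR1 was lower (69.6 ± 3.59 and 36.1 ± 1.61 CPM, edgeR adjusted p = 1.76e-24), while FOSL2 and IER3 rose 1.42-fold and 1.49-fold. The immediate early list passed the threshold without control replicate 2 (camera adjusted p = 0.0418), with library-size scaling (0.0372) and with the GC and length correction (0.0419).

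Genes of the complexes that hold YEATS4 changed by small folds and in both directions. Of 21 other subunits of SRCAP and TIP60 and their histone H2A.Z genes, 9 rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.744). Their median log2 fold change was -0.012 although camera pointed upward, and it lay between -0.030 and 0.023 when single libraries were left out, above 0 without control replicate 3 (0.023) or knockdown replicate 2 (0.018). The ATPase RUVBL2 rose 1.14-fold and MORF4L1 1.10-fold, whereas EPC1 and MBTD1 were lower (log2 fold changes -0.39, SE 0.08, and -0.24, SE 0.06). Among writers, erasers and readers of histone acylation, 5 of 26 rose and 2 fell (5 and 2 adjusted over the list alone; median 0.012, mean -0.0049, camera adjusted p = 0.499, fry upward at adjusted p = 0.0325). CDYL2, a chromodomain protein, was lower (log2 fold change -0.52, SE 0.06), the acetyltransferases KAT6B and KAT7 rose 1.17-fold and 1.14-fold, and EP300, which rose 1.08-fold, lost its call with library-size scaling (edgeR adjusted p = 0.187).

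**Figure D3:**
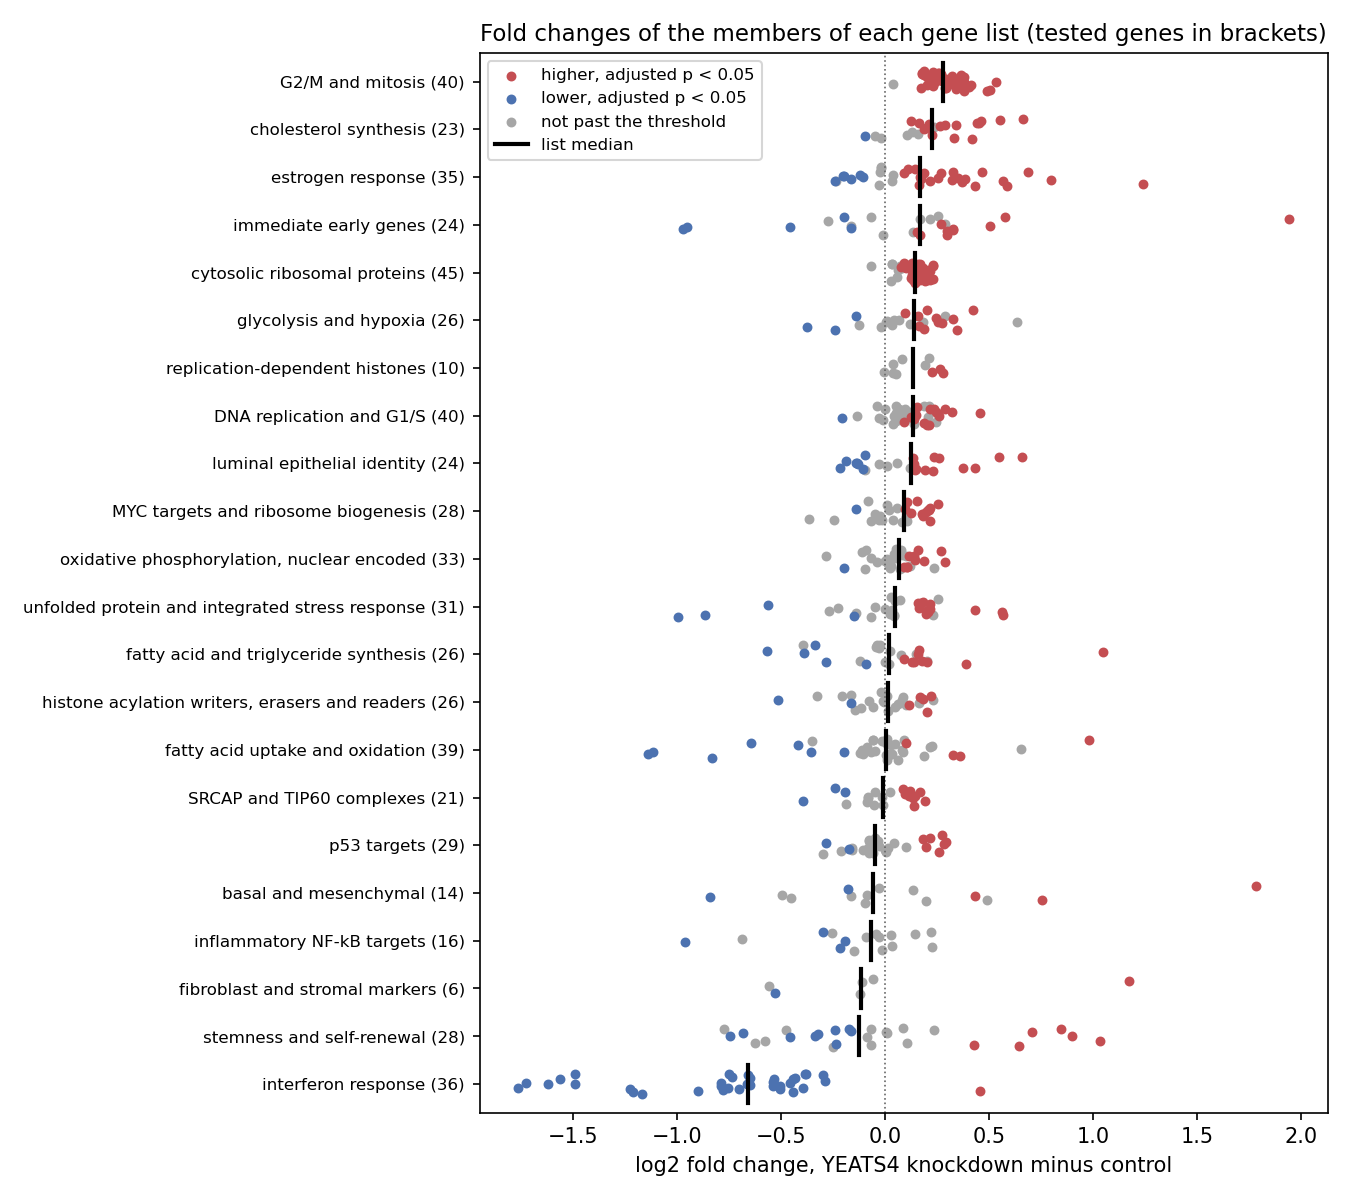
Log2 fold change of YEATS4 knockdown over control (horizontal axis) for each tested member of the 22 gene lists with at least 5 tested genes, ordered by list median (black bar); red and blue points passed an edgeR adjusted p of 0.05 upward and downward, grey points did not. The interferon-response list has a median of -0.66 and the mitosis list one of 0.28; the fatty acid medians, close to 0, turn negative under library-size scaling, where the median of all tested genes is -0.054.

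Of the 22 lists tested by camera, 11 were called, 10 upward and 1 downward, and 3 with an estimated correlation. Fry called 15. The p-values measure only the spread between these libraries, which may be technical, since the labels do not state separate cultures. Beyond counting noise, that spread was small, with a coefficient of variation of 3.28% from edgeR's common dispersion. Without a second YEATS4 shRNA group or a rescue, changes from YEATS4 loss and from other effects of the shRNA cannot be told apart.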

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

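The GC and length correction and the scaling without the ribosomal protein, mitosis and interferon genes were chosen after the data were seen; the other alternatives were planned. The YEATS4 log2 fold change lay between -1.91 and -1.78 over the alternatives that gave it and kept its call in these; it was not computed in the test against a 1.2-fold change. Without single libraries 3233 to 3970 genes were called, 1677 to 2084 higher and 1532 to 1886 lower, and 9 to 11 lists. Library-size scaling moved the higher genes from 2148 to 1396. The DESeq2 Wald test called 2508 genes, 1407 higher and 1101 lower, with 138 changed at least 2-fold. Its filter, size factors and gene set also differed from those of the main fit. An edgeR test against a 1.2-fold change called 729, 282 higher and 447 lower, which follows from its stricter hypothesis. Camera with an estimated correlation called 3 lists against 11, and fry called 15, adding fatty acid synthesis, the unfolded protein response, histone acylation and fibroblast markers. List medians that changed sign all belonged to lists that camera did not call, 3 of which fry called. With library-size scaling the median of all tested genes moved from -0.0034 to -0.054, and with it those of fatty acid synthesis (-0.031), fatty acid oxidation (-0.044), the unfolded protein response (-0.0016) and histone acylation (-0.038). With the GC and length correction, which moved the median of all tested genes to -0.018, fatty acid synthesis (-0.0086) and fatty acid oxidation (-0.021) changed sign, and the cause was not tested. Leaving out single libraries gave medians of -0.037 to 0.017 for fatty acid oxidation, -0.015 to 0.15 for basal genes and -0.030 to 0.023 for SRCAP and TIP60, for which the cause was not tested either. Of 308 list values under an alternative, 266 kept direction and side of the threshold, 21 lost and 7 gained a call, and 14 reversed. Of 1988 values of named genes, 1958 kept both, 27 lost and 3 gained a call, and 0 reversed. At the depth and spread of these libraries edgeR recovered 64% of simulated 1.2-fold changes. Far fewer genes changed there than were called in the real libraries, so 64% need not hold for the real comparison. Depth itself was not varied.

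With the replicate number as a block (replicate block), 4253 genes were called, 2212 higher and 2041 lower, including 99.2% of the 4137, and the YEATS4 log2 fold change was -1.86. Under the block 224 genes changed at least 2-fold, and 10 lists were called, without the luminal list (median 0.13, camera adjusted p = 0.0555). Libraries with the same number did not deviate together (correlations across genes of -0.0035, -0.0064 and -0.0072), so the numbers were not taken to pair the libraries.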

Other observations

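The list tests with DESeq2 size factors and with library-size scaling were planned. The other tests in this part were chosen after the results they concern were seen, and the 4 gene lists below were written then. Camera p-values of these 4 lists were adjusted over the 4 alone, not together with the lists fixed beforehand. They are therefore not directly comparable with those of the fixed lists. These lists were also written after the fold changes that camera then tested were seen, so their p-values are descriptive only. Genes of MHC class I antigen presentation were lower in knockdown cells. Of 20 tested, 15 fell and 2 rose, with a median log2 fold change of -0.42 (camera adjusted p = 3.48e-06, and adjusted p = 0.0343 with an estimated correlation). Whether the call with an estimated correlation would hold when adjusted over all lists together was not tested. The peptide transporter subunits TAP1 and TAP2 had log2 fold changes of -0.64 (SE 0.07) and -0.77 (SE 0.10), the loading factor TAPBP -0.45 (SE 0.04), HLA-C -0.44 (SE 0.05) and the immunoproteasome subunits PSMB8 and PSMB9 -1.36 (SE 0.29) and -1.26 (SE 0.23). One of its genes, and one of the chaperone genes below, is also in an earlier list. The rises were CALR and PDIA3, general chaperones of the endoplasmic reticulum, at 1.14-fold and 1.18-fold. The 3 members not called were HLA-E, HLA-A and HLA-F, with log2 fold changes of -0.05, -0.14 and -0.24. HLA-B, at 8.45 CPM in control cells, fell (log2 fold change -0.79, SE 0.15). HLA genes share sequence, so their counts are uncertain. Among interferon ligands, receptors and nucleic acid sensors, 6 of 19 fell and 0 rose, and the list was not called (median -0.07, camera adjusted p = 0.179). IFNL1, a type III interferon, was low and fell further, from 1.58 to 0.605 CPM (log2 fold change -1.42, SE 0.39, edgeR adjusted p = 0.00322), and ADAR, the RNA-editing enzyme, had a log2 fold change of -0.19 (SE 0.03).

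Cytosolic and mitochondrial chaperone genes were slightly higher, with 19 of 30 up and 0 down and a median log2 fold change of 0.11 (camera adjusted p = 1.93e-05, but adjusted p = 0.0872 with an estimated correlation). HSP90AA1 rose 1.15-fold, the mitochondrial HSPD1 1.16-fold, the cochaperone PTGES3 1.14-fold and HSPA8 1.10-fold. Splicing factor genes had 23 of 54 up and 0 down and a median of 0.06 (camera adjusted p = 8.03e-04, but adjusted p = 0.0965 with an estimated correlation). Across all tested genes fold changes were higher at higher levels (Spearman's rho 0.169), and neither list was compared with genes of like level.

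The 6 libraries can be split into groups of 3 in 10 ways. By edgeR, 1 of the 10 splits, the real one, called as many as 4137 genes, and the highest of the other 9 called 0 genes, with 228 to 346 genes at an unadjusted p under 0.05 against 5552 in the real split. With 10 splits the share cannot fall under 0.1, too few for a test at 0.05. Each of the other 9 splits put control and knockdown libraries together in a group, so any group difference widened its spread. Their low numbers were therefore largely set by the design and give no measure of chance calls.

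The fall of the interferon-response genes was weighed against technical causes. Over 4 scalings the highest list median was -0.66. These were TMM, DESeq2 size factors, library size alone, and TMM without the ribosomal protein, mitosis and interferon genes. They placed the median of all tested genes between -0.054 and -0.0024, too small a difference to undo the fall. The choice among them therefore does not account for it, and larger scaling errors were not tested. With the GC and length trend of each library removed, the list median was -0.68 (camera adjusted p = 2.68e-22). That argues against a GC or length bias as the whole cause. Whether the level fell in the knockdown or was raised in the control, for example by a response to the control shRNA, cannot be told apart, because the series has 0 untransduced libraries. A loss of basal interferon signalling after YEATS4 knockdown may account for the pattern and stays a hypothesis beside that one. The lower transcripts of IFNL1 and of most listed genes of MHC class I antigen presentation go with either. They were chosen after the fold changes were seen and are not separate support. The labels name no second YEATS4 shRNA group and no rescue, so other effects of the YEATS4 shRNA cannot be told apart from YEATS4 loss.

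No gene of chromosomes X and Y or of the mitochondrial genome had a count. Absent expression is argued against by 16 X-linked housekeeping genes, of which 0 had a count. That 0 is part of the pattern itself and not a separate test. Removal of these chromosomes before deposit may explain the pattern: on each numbered chromosome at least 73.6% of protein-coding genes had counts. At which step these counts were lost cannot be told.

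The lowest median of the mitosis list was 0.23 over the same 4 scalings, which again differed too little to undo the rise. Camera compares a list with other genes, so its p (highest camera adjusted p = 2.32e-18) says little about scaling. With the GC and length trend removed, the list median was 0.27 (camera adjusted p = 6.46e-18). That argues against a GC or length bias as the whole cause. The mean log2 fold change was 0.29 for the mitosis list and 0.13 for the DNA replication list. Their difference of 0.17 had a permutation p of 1e-05 over 100000 exchanges of genes between the lists, the smallest they can give, and genes are not independent replicates. A larger share of knockdown cells in G2 and mitosis may account for this and stays a hypothesis, since cell numbers per phase were not analysed here. Changed transcription of these genes in cells of any phase was not tested.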
